A study of Homo sapiens with 180 samples.

How the data were processed

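Total RNA of pooled cells was made into stranded mRNA libraries with a TruSeq kit, per the labels' protocols. The cultures were treated for 21 days in all with a change of medium every 3 days. Per the submitters' processing notes, kallisto 0.48 with GRCh38 (hg38) was used, and filters were not stated. The MCF-7 count table holds expected counts (kallisto's estimated counts) per transcript, deposited by the authors as whole numbers. The MCF-7 and CAMA-1 TPM tables hold TPM, deposited by the authors rounded to 0.1, and each library summed to just under 1000000. The CAMA-1 table named for counts was identical to the CAMA-1 TPM table byte for byte. It was not used, so CAMA-1 was analysed as TPM although counts had been planned. Estimated counts share reads between transcripts by a model, and TPM measures a transcript relative to all others in its library, so a change in a few abundant transcripts moves every other value.

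Values of 252913 transcripts were summed over 62703 genes, of which 62686 had their identifier in the reference table of gene names. Gene positions are those of RefSeq on GRCh38.p14 (chromosome, start and end of the whole gene). Symbols are as deposited. MCF-7 counts were fitted with edgeR 4.0.16 (TMM scaling, filterByExpr, prior count 2, quasi-likelihood F-test) in R 4.3.3, over 21849 genes. CAMA-1 values were fitted with limma 3.58.1 (robust empirical Bayes with a trend) as log2(TPM + 1), over 15796 genes with a mean of at least 1 TPM. Each line's fit took 88 libraries, with 1 level for each group and phase (day 0, or days 6 to 18) and collection time as a block, which makes 25 parameters and leaves 63 residual degrees of freedom. Each line had 16 comparisons, 32 in all. MCF-7 and CAMA-1 were never tested against each other. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within its comparison, and at least a 2-fold change. Groups of 2 libraries at day 0 borrowed their spread from the other groups. DMSO libraries of a state served every treatment of that state, so the comparisons against DMSO are not independent.

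The groups, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Genes named are a panel (ESR1, PGR, GREB1, CCND1, CCNE1, CCNE2, CDK4, CDK6, RB1, CDKN1A, MKI67, E2F1, EGFR, ERBB2, ERBB3 and DUSP6), or the 5 highest and 5 lowest called genes of a comparison, or up to 4 members of a described list with the smallest p. The highest and lowest had a mean of at least 5 CPM (counts per 1000000) or TPM in the higher group and 1 direction at every time. Genes outside this rule are said to be chosen after their values were seen. In all 32 gene lists were tested with camera, at a preset correlation of 0.01 between genes and again with an estimated correlation. Lists of other cell types were included as a check. Blood cell markers, in resistant against sensitive cells in DMSO, had 2 members higher and 0 lower of 4 in MCF-7 (the same adjusted over the list alone, camera adjusted p = 0.34) and 0 and 1 of 3 in CAMA-1 (the same adjusted over the list alone, camera adjusted p = 0.61). Fibroblast and neuroendocrine markers are given where they moved.

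Depth limits the precision. CAMA-1 depth is unknown, so no counting interval can be had there. The procedure was tested on data simulated from the mean and spread of genes in the real libraries, with 100 changed 2-fold and 100 4-fold. Its libraries were independent of each other, which those of 1 culture are not. For MCF-7 at days 6 to 18, 76% of the 2-fold and 87% of the 4-fold genes were found, with 8 false among 171. Found means an adjusted p under 0.05 with no 2-fold cut, so these are not rates for called genes. At day 0 the shares were 51% and 69%, with 5 false among 125. For CAMA-1 they were 92% and 96% (7 false among 195) at days 6 to 18, and 66% and 91% (9 among 166) at day 0. The median sizes found lay between 0.988 and 1.00 for 2-fold genes (log2 scale) and between 1.98 and 2.05 for 4-fold genes.

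Alternatives were RLE scaling, DESeq2 1.42.0, no filter on low values, limma on TPM for MCF-7, no block, all 11 times together, the 3 days as replicates, day 0 fitted alone, and leaving out each day or time. A pseudocount of 0.1 and median-ratio scaling were added for CAMA-1. Tables were handled with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The 4 untreated libraries were left out of every test because each is alone in its group.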

Results

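Transcript levels were measured by stranded sequencing of polyadenylated RNA in MCF-7 and CAMA-1, established estrogen receptor-positive luminal breast cancer lines. Each line was used as cells sensitive to ribociclib, an inhibitor of the G1 cell-cycle kinases CDK4 and CDK6, and as ribociclib-resistant cells. The cultures received the solvent DMSO, ribociclib, afatinib (an inhibitor of the ERBB family receptor kinases, among them EGFR and ERBB2) or both drugs, here called the combination. CAMA-1 cells received 0.2 µM ribociclib and 1.25 µM afatinib, and MCF-7 cells 0.5 µM and 1.5 µM. RNA was collected at 0, 6 and 24 h after a change of medium on each of days 0, 6, 12 and 18. The series holds 180 libraries, 90 for each line. Each of the 8 treatment groups of a line had 11 libraries, 2 of day 0 and 9 of days 6 to 18. Another 4 libraries of day 0, 0 h, 1 for each line and state, entered no test. Their titles name DMSO while their treatment field reads N/A, and they are called untreated here. By its title the study concerns ways past resistance to cell-cycle inhibitors. The comparisons therefore ask how resistant cells differed from sensitive cells, how each drug changed either state, and what afatinib added to ribociclib.

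Changes are log2 fold changes ± SE over 9 libraries a group (days 6 to 18) unless day 0 is named. Genes called highest or lowest moved in 1 direction at 9 of 9 times. "Rose" and "fell" mean an adjusted p under 0.05. No collection time was repeated within a group, so times stood in for replicates, and a p-value measures how steady a difference was over times, not its spread between cultures. MCF-7 libraries held 13.65 to 46.94 M estimated counts (M, 1000000), with a median of 20.14 M. Group means ran from 19.1 ± 1.33 M (SD, n = 11) in sensitive cells on the combination to 26.6 ± 11.5 M in resistant cells in DMSO. For CAMA-1, transcripts per 1000000 (TPM) were used and the depth was unknown. CAMA-1 changes are on the log2(TPM + 1) scale, which understates those of genes of low level. With limma on log2(TPM + 1), a change of test, unit and pseudocount together, resistant against sensitive MCF-7 cells gave 834 called genes in place of 2576, so numbers of genes should not be compared between lines.

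**Figure D1:**
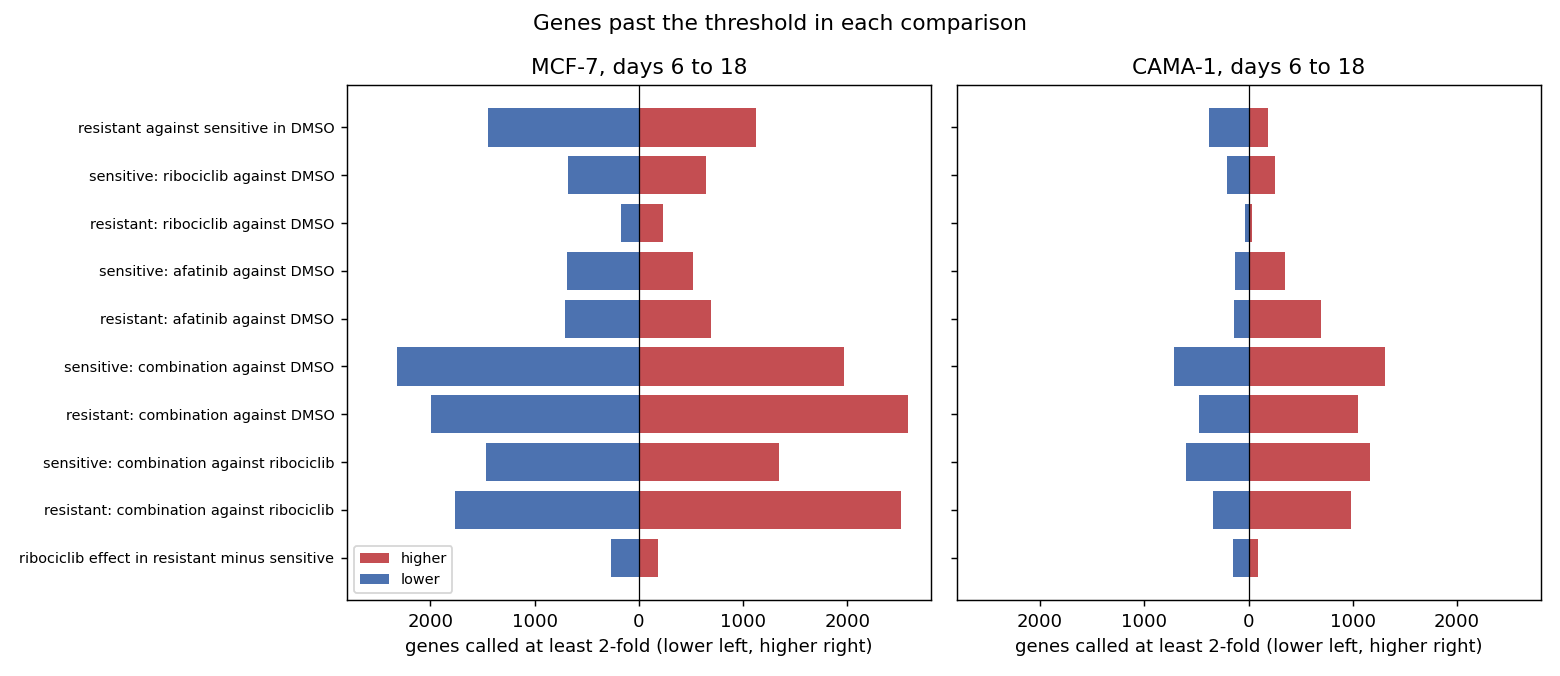
Number of genes at least 2-fold higher (right) or lower (left) at an adjusted p under 0.05 in each comparison of days 6 to 18, with MCF-7 on the left and CAMA-1 on the right. Bars run from 32 higher genes for ribociclib in resistant CAMA-1 cells to 2585 for the combination in resistant MCF-7 cells.

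In DMSO, resistant MCF-7 cells held less progesterone receptor message than sensitive cells and more of the G1 cyclin CCNE1. PGR (chromosome 11, 101029624 to 101129813), a classic estrogen receptor target, changed by -1.17 ± 0.19, and GREB1, another such target, by -0.46 ± 0.08. CCNE1 (chromosome 19, 29811991 to 29824312), which drives S-phase entry with CDK2, stood at 26.9 ± 3.45 against 12.0 ± 1.69 CPM (SD, n = 9 each), a change of 1.17 ± 0.07. CDK6 (0.95 ± 0.08), a target of ribociclib, was higher, as were the receptor genes EGFR (0.99 ± 0.16) and ERBB3 (0.69 ± 0.07) and CCND1 (0.43 ± 0.09), the partner cyclin of CDK4/6. The largest adjusted p of these genes was 5.0e-05. Among estrogen receptor targets 10 rose and 16 fell of 31 (11 and 16 adjusted over the list alone), median -0.20 (camera adjusted p = 0.18). Those that fell included BCL2 (-5.31 ± 0.27) and ABCG2 (-4.15 ± 0.28), of which BCL2 restrains apoptosis and ABCG2 exports drugs.

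Interferon-stimulated and antigen-presenting genes were lower in resistant MCF-7 cells, and genes of glycolysis and low oxygen were higher. Drift with days may add to this, as the interferon list rose in sensitive and the hypoxia list in resistant DMSO cells. In the interferon response list 2 rose and 28 fell of 36 (the same adjusted over the list alone), median -1.12 (camera adjusted p = 1.1e-05, adjusted p = 0.82 with an estimated correlation). Among them were IFIT1 (-3.03 ± 0.33) and USP18 (-2.79 ± 0.21), of which IFIT1 is antiviral. In the antigen presentation list 2 rose and 12 fell of 18 (2 and 13 adjusted over the list alone), median -0.72 (camera adjusted p = 0.0010, adjusted p = 0.53 with an estimated correlation). The peptide transporter gene TAP1 (-2.11 ± 0.15) and HLA-DRB1 (-3.12 ± 0.19) were among those lower. In the hypoxia and glycolysis list 25 rose and 1 fell of 27 (the same adjusted over the list alone), median 1.08 (camera adjusted p = 4.0e-10, adjusted p = 0.53 with an estimated correlation). Examples were ALDOC (2.18 ± 0.21) and HK2 (1.71 ± 0.14), enzymes of glycolysis. F13A1 (8.14 ± 0.46), SPRR1A (7.51 ± 0.45), SPRR1B (7.11 ± 0.47) and VCAN (7.06 ± 0.25) had the highest changes. DLC1 (-8.32 ± 0.24), MGP (-7.17 ± 0.27) and FSTL5 (-6.87 ± 0.40) had the lowest. VCAN encodes a matrix proteoglycan. In all, 1125 genes were at least 2-fold higher and 1451 lower of 21849 tested, 1916 of them in 1 direction at every time.

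Resistant CAMA-1 cells in DMSO carried less RB1 message than sensitive cells. RB1 (chromosome 13, 48303751 to 48481890), the retinoblastoma gene whose product CDK4/6 inactivate, stood at 16.6 ± 2.23 against 37.0 ± 4.86 TPM (SD, n = 9 each), a change of -1.11 ± 0.07 (adjusted p = 2.7e-23). Among cytosolic ribosomal protein genes 28 rose and 2 fell of 33 (the same adjusted over the list alone), median 0.45 (camera adjusted p = 2.2e-19, adjusted p = 0.30 with an estimated correlation), for instance RPL7A (1.01 ± 0.06) and RPS8 (0.81 ± 0.06). Among estrogen receptor targets 5 rose and 18 fell of 31 (the same adjusted over the list alone), median -0.35 (camera adjusted p = 0.0080, adjusted p = 0.83 with an estimated correlation), with IGF1R (-1.59 ± 0.13) and ELOVL2 (-1.95 ± 0.15) lower. Fibroblast markers, listed to detect another cell type, gave 0 higher and 2 lower of 4 (the same adjusted over the list alone), median -1.08 (camera adjusted p = 9.1e-04, adjusted p = 0.0056 with an estimated correlation). DUSP4, a phosphatase gene that ERK induces, changed by -3.64 ± 0.15. BRINP3 (6.24 ± 0.18), PCDH17 (4.46 ± 0.06), PYCARD (4.44 ± 0.13), PCP4 (4.16 ± 0.20) and MGST1 (3.98 ± 0.15) had the highest changes. NDUFA4L2 (-6.07 ± 0.60), COL3A1 (-5.09 ± 0.15) and NXPH4 (-4.26 ± 0.32) had the lowest. PYCARD is the inflammasome adaptor ASC, MGST1 a microsomal glutathione transferase and COL3A1 a fibrillar collagen. In this line 186 genes were at least 2-fold higher and 384 lower of 15796 tested. A pseudocount of 0.1 in place of 1 raised the total from 570 to 1026.

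Ribociclib lowered cell-cycle genes in sensitive MCF-7 cells through days 6 to 18 and raised the genes of its own target kinase and cyclin. CCNE2, a cyclin gene under E2F control, changed by -0.99 ± 0.14 and the proliferation marker MKI67 by -1.31 ± 0.15. CDK6 rose by 1.27 ± 0.08, CCND1 by 0.74 ± 0.09, ERBB2 by 0.60 ± 0.08 and CCNE1 by 0.52 ± 0.07 (largest adjusted p of these = 1.9e-08). In the G2/M and mitosis list 0 rose and 40 fell of 40 (the same adjusted over the list alone), median -1.24 (camera adjusted p = 1.3e-31, adjusted p = 0.16 with an estimated correlation), including NUSAP1 (-1.91 ± 0.16) and PTTG1 (-1.67 ± 0.13). In the G1/S and DNA replication list 1 rose and 42 fell of 45 (the same adjusted over the list alone), median -0.69 (camera adjusted p = 4.7e-18, adjusted p = 0.25 with an estimated correlation). The primase subunit PRIM1 (-1.57 ± 0.13) and the replication clamp PCNA (-1.19 ± 0.11) were among these. Lysosome and autophagy genes moved up: 25 rose and 1 fell of 31 (the same adjusted over the list alone), median 0.41 (camera adjusted p = 1.8e-13, adjusted p = 0.14 with an estimated correlation), with the lysosomal protease CTSD (1.05 ± 0.10). Among drug efflux and metabolism genes 10 rose and 0 fell of 14 (11 and 0 adjusted over the list alone), median 0.60 (camera adjusted p = 1.1e-04, adjusted p = 0.012 with an estimated correlation), with ABCG2 (1.57 ± 0.19). CLEC3A (4.54 ± 0.27), OLFML3 (3.09 ± 0.22) and CLIP4 (3.03 ± 0.19) had the highest changes. MGP (-3.52 ± 0.20), SCNN1G (-2.90 ± 0.34) and PLCXD3 (-2.46 ± 0.25) had the lowest. Mitochondrially encoded mRNAs, a sign of RNA quality, moved up: 10 rose and 0 fell of 13 (11 and 0 adjusted over the list alone), median 0.39 (camera adjusted p = 0.0026, adjusted p = 0.73 with an estimated correlation). At day 18 they made up 10.7 ± 1.12% of TPM against 7.81 ± 0.758% in DMSO (SD, n = 3). In all, 646 genes were at least 2-fold higher and 679 lower.

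In resistant MCF-7 cells on ribociclib, 233 genes were at least 2-fold higher and 169 lower (237 in total with the 3 days as replicates). CCNE1 rose by 0.75 ± 0.07, CDK6 by 0.78 ± 0.08 and CCND1 by 0.71 ± 0.09, while MKI67 changed by -0.74 ± 0.15 (largest adjusted p = 1.2e-04). In the G2/M list 0 rose and 32 fell of 40 (0 and 38 adjusted over the list alone), median -0.47 (camera adjusted p = 6.0e-15, adjusted p = 0.65 with an estimated correlation), among them NUSAP1 (-0.85 ± 0.15) and PTTG1 (-0.74 ± 0.12). In the G1/S list 1 rose and 32 fell of 45 (1 and 36 adjusted over the list alone), median -0.33 (camera adjusted p = 3.9e-12, adjusted p = 0.65 with an estimated correlation). The highest changes included TGFB2 (2.64 ± 0.22), KRT13 (2.55 ± 0.37) and GSTM3 (2.16 ± 0.15), a growth factor, an epithelial keratin and a glutathione transferase gene. The lowest included AZGP1 (-2.37 ± 0.25) and PLAT (-1.95 ± 0.20), the latter encoding tissue plasminogen activator. Tested directly as resistant minus sensitive, mitotic genes responded less in resistant cells: in the G2/M list 37 rose and 0 fell of 40 (40 and 0 adjusted over the list alone), median 0.70 (camera adjusted p = 1.9e-24, adjusted p = 0.30 with an estimated correlation), where "rose" means a less negative response. Examples were NUF2 (1.14 ± 0.21) and CENPA (0.99 ± 0.16). In the G1/S list 12 rose and 0 fell of 45 (21 and 0 adjusted over the list alone), median 0.35 (camera adjusted p = 1.6e-09, adjusted p = 0.52 with an estimated correlation). Drug efflux and metabolism genes went the other way: 0 rose and 4 fell of 14 (0 and 8 adjusted over the list alone), median -0.55 (camera adjusted p = 2.7e-05, adjusted p = 0.0058 with an estimated correlation). The response differed most for MGP (2.86 ± 0.57), CXCL12 (2.30 ± 0.28), BPIFB1 (-3.59 ± 0.40) and STUM (-2.78 ± 0.38). MGP was already far lower in resistant DMSO cells, which may limit its fall. Responses differed at least 2-fold for 445 genes, 181 higher and 264 lower in resistant cells. Totals were 167 without day 12, 43 with the 3 days as replicates and 141 with limma on TPM.

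Sensitive CAMA-1 cells raised estrogen receptor targets and antigen presentation genes under ribociclib. The former stood 0.31, 0.59 and 0.48 above DMSO at days 6, 12 and 18. PGR rose by 2.04 ± 0.26, GREB1 by 1.22 ± 0.25 and CCND1 by 0.72 ± 0.11 (largest adjusted p = 5.2e-05). Among estrogen receptor targets 18 rose and 3 fell of 31 (19 and 3 adjusted over the list alone), median 0.54 (camera adjusted p = 7.7e-10, adjusted p = 0.083 with an estimated correlation), including PDZK1 (3.75 ± 0.24) and CXCL12 (2.17 ± 0.20). Among antigen presentation genes 11 rose and 1 fell of 15 (12 and 1 adjusted over the list alone), median 0.56 (camera adjusted p = 4.2e-09, adjusted p = 0.076 with an estimated correlation), with the class I genes HLA-B (0.89 ± 0.10) and HLA-F (1.24 ± 0.14). Genes of hypoxia and glycolysis were lower than in DMSO: 0 rose and 22 fell of 27 (the same adjusted over the list alone), median -1.03 (camera adjusted p = 1.4e-07, adjusted p = 0.45 with an estimated correlation), with LDHA (-1.30 ± 0.19) and PGK1 (-1.49 ± 0.25). Their median difference was -0.21 ± 0.33 at day 6 (SD, n = 3), -1.59 ± 0.41 at day 12 and -1.22 ± 0.34 at day 18, while the list rose in DMSO from day 6 to day 18, with a median of 1.93 (camera adjusted p = 1.7e-28, adjusted p = 0.043 with an estimated correlation). The highest changes included OLFML3 (3.08 ± 0.19), PRSS23 (3.06 ± 0.27), IL32 (3.02 ± 0.26) and CCL2 (3.00 ± 0.36). The lowest included MT1X (-3.02 ± 0.40), a metallothionein gene. Mitotic genes were furthest below DMSO at day 6. The G2/M median difference was -1.48 ± 0.53, 0.001 ± 0.40 and 0.37 ± 0.35 at days 6, 12 and 18 (SD, n = 3). The day-6 library of 24 h stood apart, as given below. The DMSO control fell meanwhile, from 0.79 to 0.87 against its day-0 mean at day 6 to -0.51 to -0.17 at day 18 (range, n = 3). Over these days 0 rose and 7 fell of 40 (0 and 0 adjusted over the list alone), median -0.41 (camera adjusted p = 0.096). By cameraPR the list passed without day 12 (median -0.60, adjusted p = 0.014), without day 18 (-0.73, 3.7e-05) and with median-ratio scaling (-0.34, 0.027). The test changed too, so this cannot be laid to the day left out or the scaling alone. Mitochondrially encoded mRNAs, taken as a sign of RNA quality, moved up: 7 rose and 0 fell of 13 (8 and 0 adjusted over the list alone), median 0.40 (camera adjusted p = 3.7e-04, adjusted p = 0.52 with an estimated correlation). Without day 6 their median was 0.35 (cameraPR adjusted p = 0.053). At day 18 they made up 23.8 ± 0.598% of TPM against 17.7 ± 1.77% in DMSO (SD, n = 3). In all, 249 genes were at least 2-fold higher and 204 lower, or 357 and 160 with mitochondrial, ribosomal RNA and microRNA genes left out and TPM rescaled. The counts were 342 and 360 without day 6 and 763 in total with a pseudocount of 0.1. The effect changed at least 2-fold from day 6 to day 18 for 1506 genes.

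In resistant CAMA-1 cells ribociclib changed few genes, and 32 genes were at least 2-fold higher and 37 lower (44 in total without day 12, 25 with the 3 days as replicates, 143 with a pseudocount of 0.1). The estrogen receptor targets PDZK1 (1.43 ± 0.24) and SUSD3 (1.14 ± 0.17) were higher. In their list 5 rose and 2 fell of 31 (9 and 3 adjusted over the list alone), median 0.16 (camera adjusted p = 1.4e-04, adjusted p = 0.51 with an estimated correlation). Among cholesterol synthesis genes 10 rose and 0 fell of 24 (15 and 0 adjusted over the list alone), median 0.35 (camera adjusted p = 4.1e-13, adjusted p = 0.14 with an estimated correlation), with SQLE (0.65 ± 0.12). That median was 0.23 without day 18. The matrix protein gene SPARC (2.44 ± 0.25) and the mammaglobin gene SCGB2A2 (1.57 ± 0.25) were among the highest, and CDSN (-4.40 ± 0.21), PCP4 (-2.61 ± 0.20) and BGN (-2.02 ± 0.21) among the lowest. Tested as resistant minus sensitive, antigen presentation genes responded less in resistant cells: 0 rose and 10 fell of 15 (the same adjusted over the list alone), median -0.60 (camera adjusted p = 2.6e-08, adjusted p = 0.049 with an estimated correlation). Estrogen receptor targets did too: 1 rose and 10 fell of 31 (1 and 13 adjusted over the list alone), median -0.40 (camera adjusted p = 2.8e-07, adjusted p = 0.19 with an estimated correlation). The response differed at least 2-fold for 86 genes higher and 147 lower in resistant cells. With TPM rescaled as above these were 69 and 218. The total of 233 became 494 without day 6, 110 without day 12, 25 with the 3 days as replicates and 400 with a pseudocount of 0.1.

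**Figure D2:**
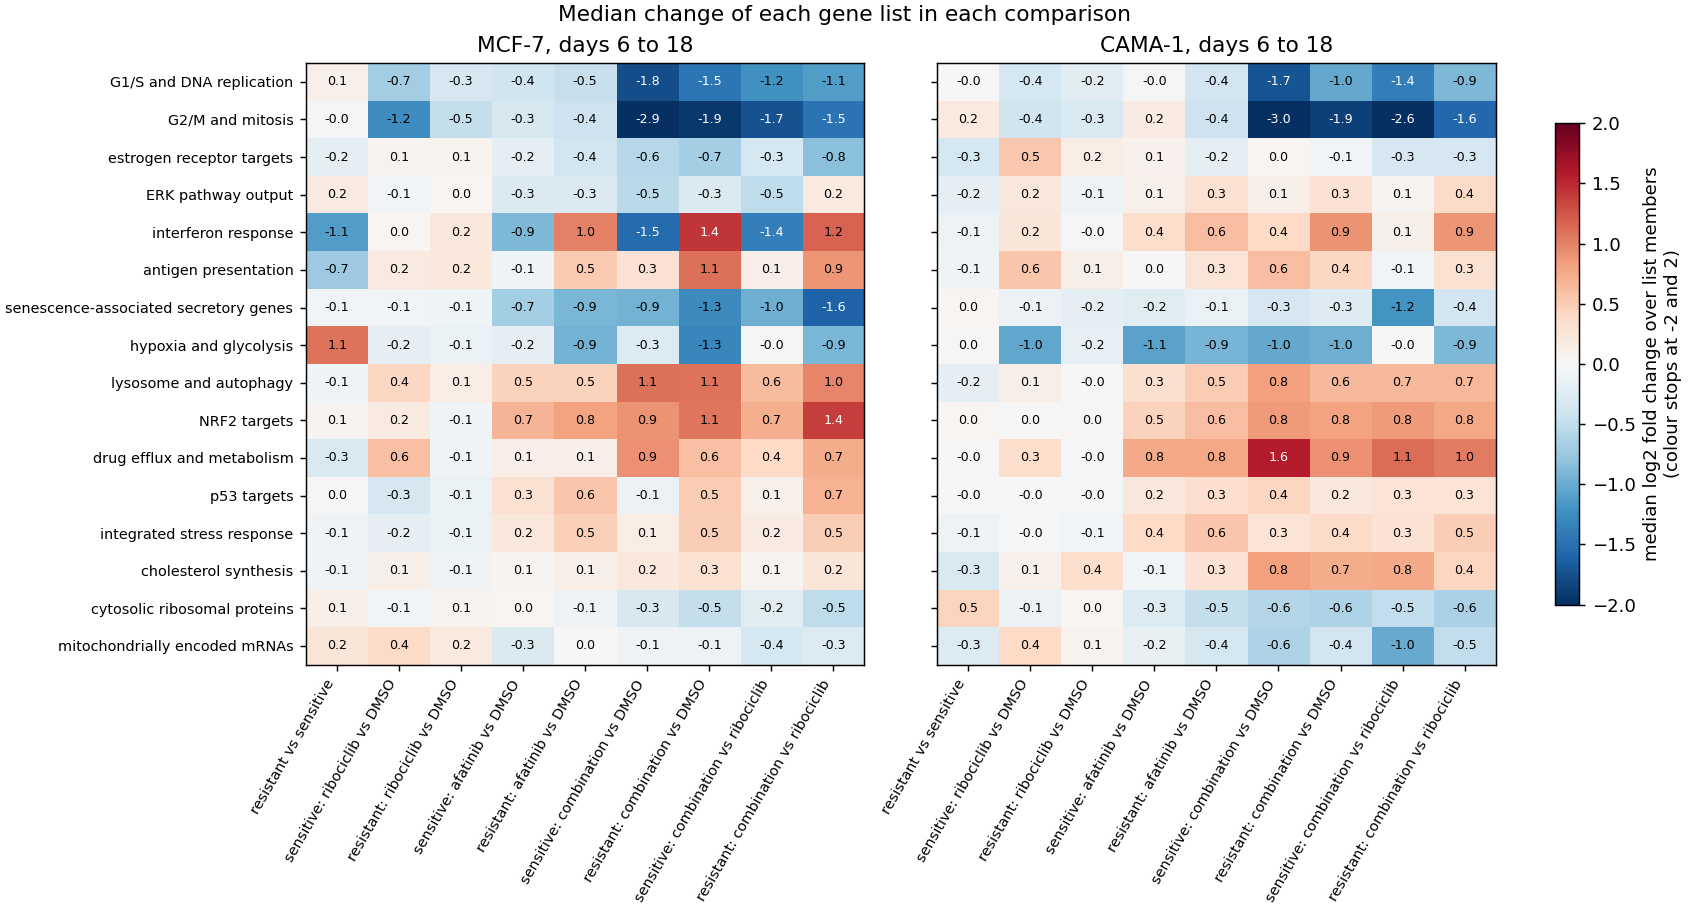
Median log2 fold change over the members of each gene list (vertical) in each comparison of days 6 to 18 (horizontal), for MCF-7 (left) and CAMA-1 (right), with red above and blue below 0 and colours stopping at -2 and 2. The G2/M and mitosis list had its lowest median, -2.98, for the combination in sensitive CAMA-1 cells.

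Afatinib lowered CCND1 in sensitive MCF-7 cells and raised genes of the oxidative stress response and the lysosome. CCND1, which growth factor signalling induces, changed by -1.20 ± 0.09 and EGFR by -0.88 ± 0.18 (largest adjusted p = 5.3e-05). Among targets of NRF2, a transcription factor of the oxidative stress response, 18 rose and 0 fell of 20 (the same adjusted over the list alone), median 0.68 (camera adjusted p = 1.9e-17, adjusted p = 0.0055 with an estimated correlation), including NQO1 (1.24 ± 0.09). Among lysosome and autophagy genes 26 rose and 0 fell of 31 (28 and 0 adjusted over the list alone), median 0.47 (camera adjusted p = 1.1e-19, adjusted p = 0.024 with an estimated correlation), with NPC2 (0.74 ± 0.05). Among integrated stress response genes, which ATF4 controls, 16 rose and 1 fell of 28 (the same adjusted over the list alone), median 0.21 (camera adjusted p = 1.0e-05, adjusted p = 0.27 with an estimated correlation), including DDIT3 (1.32 ± 0.17). Interferon response genes went down: 1 rose and 26 fell of 36 (1 and 28 adjusted over the list alone), median -0.90 (camera adjusted p = 9.6e-08, adjusted p = 0.27 with an estimated correlation), or a median of -0.49 without day 18. IFITM1 (-2.19 ± 0.33) and BST2 (-2.34 ± 0.34) were among them. In DMSO this list itself rose from day 6 to day 18, with a median of 1.10 (camera adjusted p = 7.3e-21, adjusted p = 0.064 with an estimated correlation). SCNN1A (2.68 ± 0.20), HMOX1 (2.41 ± 0.19) and LCN2 (2.36 ± 0.32) had the highest changes. HMGCLL1 (-4.87 ± 0.33), MGP (-3.83 ± 0.21) and TNFRSF11B (-3.45 ± 0.19) had the lowest. HMOX1 is haem oxygenase. Mitochondrially encoded mRNAs, taken as a sign of RNA quality, moved down: 0 rose and 7 fell of 13 (the same adjusted over the list alone), median -0.29 (camera adjusted p = 0.0025, adjusted p = 0.49 with an estimated correlation). Their median was -0.10 (cameraPR adjusted p = 0.23) without day 6, when the DMSO library of 24 h was high in them, and -0.52 without day 18. At day 6 they made up 5.24 ± 0.385% of TPM against 8.88 ± 2.28% in DMSO (SD, n = 3), and at day 18 ribosomal RNA 0.339 ± 0.0187% against 0.183 ± 0.0165%. In all, 524 genes were at least 2-fold higher and 686 lower.

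In resistant MCF-7 cells afatinib raised interferon-stimulated genes. In this list 27 rose and 1 fell of 36 (28 and 1 adjusted over the list alone), median 1.01 (camera adjusted p = 1.5e-09, adjusted p = 0.16 with an estimated correlation), among them the antiviral genes RSAD2 (2.85 ± 0.36), IFIH1 (1.41 ± 0.17) and ISG15 (1.37 ± 0.15). Antigen presentation genes moved up too: 11 rose and 1 fell of 18 (12 and 1 adjusted over the list alone), median 0.53 (camera adjusted p = 6.2e-06, adjusted p = 0.093 with an estimated correlation), with the transporter genes TAP1 (1.91 ± 0.15) and TAP2 (1.19 ± 0.14). NLRC5 (3.66 ± 0.28), a regulator of class I antigen presentation (chromosome 16, 56989557 to 57083520), had the highest change of all. The difference between states was tested: resistant minus sensitive, the interferon list had a median of 1.74 (camera adjusted p = 2.4e-48, adjusted p = 7.8e-04 with an estimated correlation), with IFIT1 (3.42 ± 0.44, adjusted p = 9.9e-08) and IFI27 (3.28 ± 0.46, adjusted p = 5.1e-07). NRF2 targets moved up: 19 rose and 0 fell of 20 (the same adjusted over the list alone), median 0.81 (camera adjusted p = 7.8e-18, adjusted p = 0.0048 with an estimated correlation). So did p53 targets: 20 rose and 1 fell of 24 (21 and 1 adjusted over the list alone), median 0.56 (camera adjusted p = 1.6e-11, adjusted p = 0.028 with an estimated correlation), with CDKN1A, which inhibits CDK2, up by 1.09 ± 0.12. CCND1 changed by -1.39 ± 0.09, and the ERK-induced genes DUSP4 (-2.37 ± 0.17), DUSP6 (-0.90 ± 0.19) and EGR1 (-1.85 ± 0.21) fell (largest adjusted p = 7.0e-05). Among hypoxia and glycolysis genes 0 rose and 23 fell of 27 (the same adjusted over the list alone), median -0.95 (camera adjusted p = 1.1e-12, adjusted p = 0.13 with an estimated correlation). In DMSO this list rose from day 6 to day 18, with a median of 0.83 (camera adjusted p = 1.0e-14, adjusted p = 0.13 with an estimated correlation). LCN2 (3.00 ± 0.30) and HMOX1 (2.93 ± 0.19) were also among the highest, and SLITRK5 (-3.96 ± 0.28) and TFF3 (-3.75 ± 0.28) among the lowest. In all, 692 genes were at least 2-fold higher and 705 lower.

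**Figure D3:**
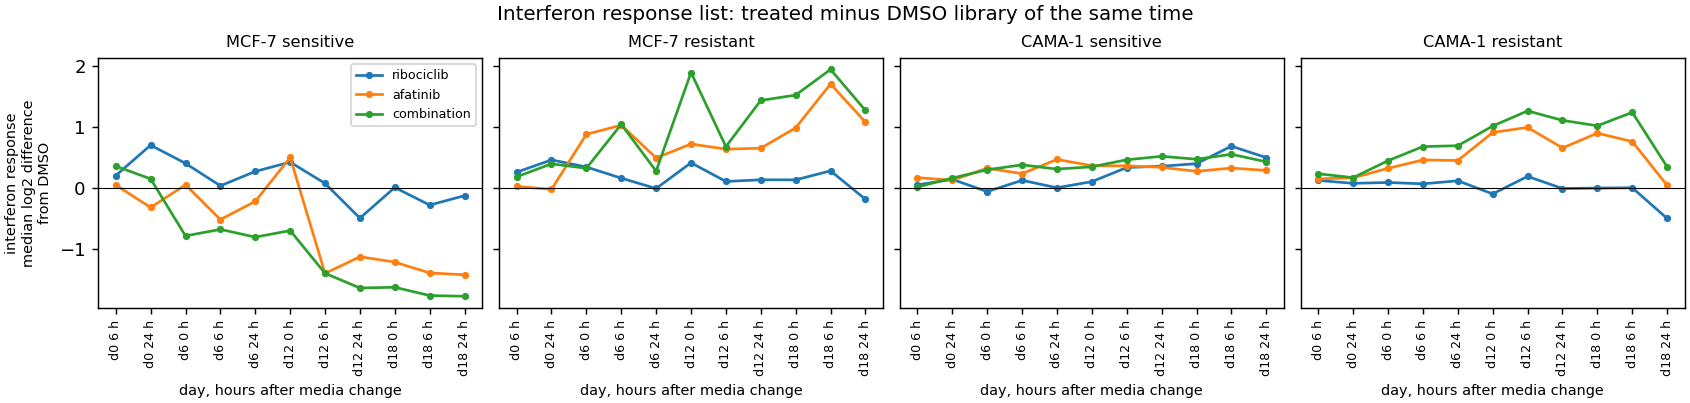
Median log2 difference of the interferon response list between each treated library and the DMSO library of the same time (vertical), by day and hours after media change (horizontal), for each line and state. On afatinib the resistant MCF-7 points of days 6 to 18 all lie above 0, from 0.49 to 1.70, and the sensitive ones lie between -1.43 and -1.13 from day 12, 6 h, onward. Before that the latter are less steady, and that of day 12, 0 h, lies above 0.

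Sensitive CAMA-1 cells on afatinib had less of hypoxia and glycolysis and of ribosomal protein transcripts than those in DMSO. Among the former 0 rose and 21 fell of 27 (the same adjusted over the list alone), median -1.07 (camera adjusted p = 2.5e-23, adjusted p = 0.067 with an estimated correlation), including CA9 (-4.02 ± 0.62) and LDHA (-1.70 ± 0.19), a hypoxia-induced carbonic anhydrase and a lactate dehydrogenase gene. The median difference was -0.03 ± 0.30, -1.48 ± 0.35 and -1.67 ± 0.57 at days 6, 12 and 18 (SD, n = 3). In DMSO the list rose over these days (above). Among cytosolic ribosomal protein genes 0 rose and 29 fell of 33 (the same adjusted over the list alone), median -0.27 (camera adjusted p = 4.4e-30, adjusted p = 0.053 with an estimated correlation). Among NRF2 targets 9 rose and 0 fell of 15 (the same adjusted over the list alone), median 0.47 (camera adjusted p = 0.14), with NQO1 (1.44 ± 0.15). Neuroendocrine and neuronal markers gave 0 higher and 3 lower of 5 (the same adjusted over the list alone), median -0.38 (camera adjusted p = 0.0012, adjusted p = 0.0041 with an estimated correlation). The lowest changes were in NDUFA4L2 (-5.04 ± 0.60), CASP14 (-4.36 ± 0.66) and the estrogen-induced TFF3 (-3.21 ± 0.35) and TFF1 (-3.04 ± 0.30). In the estrogen receptor list, however, 14 rose and 5 fell of 31 (the same adjusted over the list alone), median 0.08 (camera adjusted p = 0.12), with a median difference of -0.20 ± 0.14 at day 6 (SD, n = 3), 0.17 ± 0.03 at day 12 and 0.50 ± 0.12 at day 18. Without day 18 its median was -0.04 (cameraPR adjusted p = 8.6e-04). The highest included PLA2G2A (2.93 ± 0.43). Ribosomal RNA was 0.560% of TPM at day 6 and 0.331% at day 18 (DMSO 0.131% and 0.161%). In all, 349 genes were at least 2-fold higher and 133 lower. The median of all genes shifted by 0.20 here, by 0.27 in resistant cells, and by 0.22 and 0.26 on the combination. With median-ratio scaling 187 genes were higher and 197 lower. Without day 6 the counts were 522 and 206, and a pseudocount of 0.1 gave 1016 in total.

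Resistant CAMA-1 cells on afatinib raised CDKN1A by 1.78 ± 0.29 and ERBB2, a target of the drug, by 0.89 ± 0.10, while PGR changed by -1.01 ± 0.26 and GREB1 by -1.24 ± 0.25 (largest adjusted p = 6.7e-04). Ribosomal protein genes fell: 0 rose and 33 fell of 33 (the same adjusted over the list alone), median -0.48 (camera adjusted p = 1.4e-48, adjusted p = 0.0070 with an estimated correlation). Mitochondrially encoded mRNAs, taken as a sign of RNA quality, moved with them: 2 rose and 7 fell of 13 (the same adjusted over the list alone), median -0.35 (camera adjusted p = 2.2e-05, adjusted p = 0.51 with an estimated correlation). Their median was -0.54 without day 6 and -0.05 (cameraPR adjusted p = 0.12) without day 18. Among hypoxia and glycolysis genes 1 rose and 21 fell of 27 (the same adjusted over the list alone), median -0.93 (camera adjusted p = 2.7e-17, adjusted p = 0.15 with an estimated correlation). Their median difference was 0.02 ± 0.11 at day 6 (SD, n = 3), -1.24 ± 0.81 at day 12 and -1.56 ± 0.81 at day 18, and in DMSO the list rose from day 6 to day 18, with a median of 2.11 (camera adjusted p = 2.7e-35, adjusted p = 0.015 with an estimated correlation). Of the cholesterol synthesis genes 14 rose and 1 fell of 24 (the same adjusted over the list alone), median 0.30 (camera adjusted p = 0.57), where all genes had a median of 0.27, with DHCR24 (1.18 ± 0.09) and TM7SF2 (1.60 ± 0.10). Among lysosome and autophagy genes 26 rose and 0 fell of 30 (the same adjusted over the list alone), median 0.50 (camera adjusted p = 1.7e-04, adjusted p = 0.51 with an estimated correlation). Of the p53 targets 12 rose and 0 fell of 20 (the same adjusted over the list alone), median 0.33 (camera adjusted p = 0.58). The lowest changes included MGP (-5.26 ± 0.24), CRABP1 (-3.56 ± 0.23) and TFF1 (-3.26 ± 0.30). In all, 695 genes were at least 2-fold higher and 137 lower, or 322 and 241 with median-ratio scaling, 1309 and 190 without day 6, and 1594 in total with a pseudocount of 0.1.

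**Figure D4:**
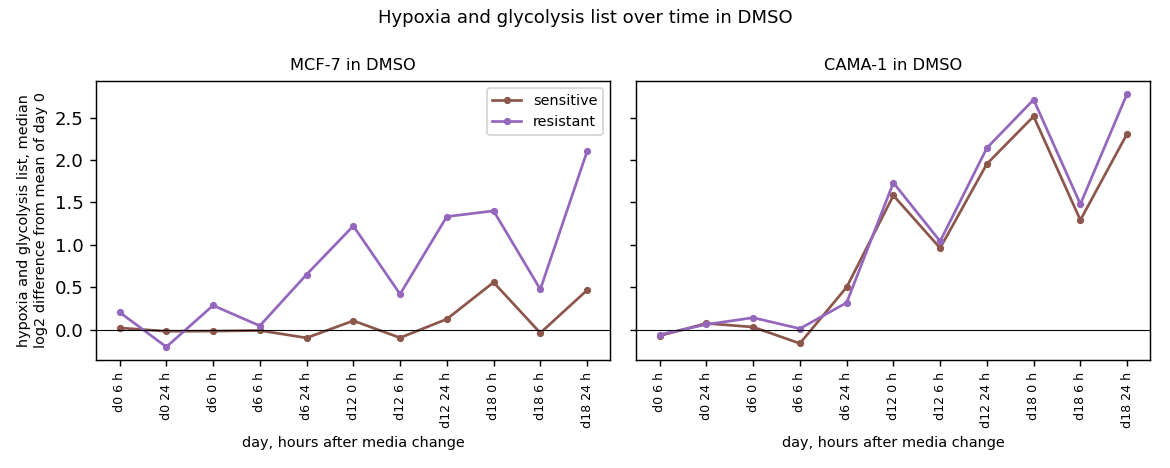
Median log2 difference of the hypoxia and glycolysis list from its mean at day 0 (vertical) in the DMSO cultures, by day and hours after media change (horizontal), for sensitive and resistant cells of MCF-7 (left) and CAMA-1 (right). In CAMA-1 the list rose by 2.52 in sensitive and 2.71 in resistant cells at day 18, 0 h, and was lower at 6 h after the change of medium of that day.

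The combination lowered cell-cycle genes in sensitive MCF-7 cells beyond ribociclib alone. CCNE2 changed by -3.27 ± 0.16, MKI67 by -3.30 ± 0.16, ESR1, the estrogen receptor gene, by -1.14 ± 0.12, PGR by -2.25 ± 0.21 and RB1 by -0.94 ± 0.09. ERBB2 rose by 0.93 ± 0.08 and CDK6 by 1.03 ± 0.08 (largest adjusted p of these = 1.9e-13). Of the mitotic genes 0 rose and 40 fell of 40 (the same adjusted over the list alone), median -2.85 (camera adjusted p = 2.7e-36, adjusted p = 0.084 with an estimated correlation), including PTTG1 (-3.48 ± 0.14). The G1/S list went the same way: 1 rose and 44 fell of 45 (the same adjusted over the list alone), median -1.77 (camera adjusted p = 8.5e-28, adjusted p = 0.089 with an estimated correlation), including the thymidylate synthase gene TYMS (-3.68 ± 0.16). Against ribociclib alone, the G2/M list again moved down: 0 rose and 40 fell of 40 (the same adjusted over the list alone), median -1.74 (camera adjusted p = 6.7e-35, adjusted p = 0.12 with an estimated correlation). Among lysosome and autophagy genes 30 rose and 0 fell of 31 (the same adjusted over the list alone), median 1.10 (camera adjusted p = 1.7e-20, adjusted p = 0.044 with an estimated correlation). Among interferon response genes 4 rose and 28 fell of 36 (the same adjusted over the list alone), median -1.54 (camera adjusted p = 2.3e-04, adjusted p = 0.59 with an estimated correlation), with IFITM1 (-4.46 ± 0.40). The immunoglobulin gene IGHM (7.04 ± 0.34), the homeobox genes HOXB2 (5.49 ± 0.25) and HOXB3 (5.28 ± 0.27) and ALDH1A2 (5.49 ± 0.32), which makes retinoic acid, were among the highest. MGP (-6.43 ± 0.26), THEG (-4.61 ± 0.26) and HMGCLL1 (-4.58 ± 0.33) were among the lowest. At day 18 ribosomal RNA made up 1.06 ± 0.0488% of TPM against 0.183 ± 0.0165% in DMSO (SD, n = 3), and microRNA genes 1.04 ± 0.0502% against 0.316 ± 0.0448%. In all, 1963 genes were at least 2-fold higher and 2321 lower than in DMSO, and 1345 higher and 1467 lower than on ribociclib.

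In resistant MCF-7 cells the combination lowered cell-cycle genes and raised interferon, antigen presentation and oxidative stress genes. CCNE2 changed by -2.34 ± 0.15, MKI67 by -2.16 ± 0.16, CCND1 by -1.42 ± 0.09, ESR1 by -1.52 ± 0.12, PGR by -1.77 ± 0.21 and RB1 by -1.08 ± 0.09, and CDKN1A rose by 1.41 ± 0.12 (largest adjusted p = 4.5e-11). Mitotic genes of the G2/M list moved down: 0 rose and 40 fell of 40 (the same adjusted over the list alone), median -1.93 (camera adjusted p = 8.7e-26, adjusted p = 0.13 with an estimated correlation). So did the G1/S list: 1 rose and 43 fell of 45 (the same adjusted over the list alone), median -1.45 (camera adjusted p = 1.5e-22, adjusted p = 0.13 with an estimated correlation). In the interferon list 28 rose and 3 fell of 36 (the same adjusted over the list alone), median 1.42 (camera adjusted p = 3.8e-06, adjusted p = 0.36 with an estimated correlation), with IFIH1 (2.33 ± 0.17) and ISG15 (2.09 ± 0.15). Resistant minus sensitive, that list had a median of 2.78 (camera adjusted p = 1.4e-27, adjusted p = 0.034 with an estimated correlation). Among antigen presentation genes 17 rose and 0 fell of 18 (the same adjusted over the list alone), median 1.11 (camera adjusted p = 1.5e-07, adjusted p = 0.061 with an estimated correlation), with TAP1 (2.67 ± 0.16). NRF2 targets moved up: 17 rose and 0 fell of 20 (18 and 0 adjusted over the list alone), median 1.07 (camera adjusted p = 3.3e-10, adjusted p = 0.061 with an estimated correlation). Hypoxia and glycolysis genes moved down: 1 rose and 22 fell of 27 (the same adjusted over the list alone), median -1.30 (camera adjusted p = 1.9e-06, adjusted p = 0.36 with an estimated correlation). Against ribociclib alone, estrogen receptor targets were lower: 3 rose and 23 fell of 31 (4 and 24 adjusted over the list alone), median -0.84 (camera adjusted p = 3.8e-06, adjusted p = 0.071 with an estimated correlation). The highest changes included IGHM (5.90 ± 0.29) and NLRC5 (4.94 ± 0.28). The lowest included PLAT (-6.46 ± 0.27), TFF3 (-4.84 ± 0.30) and COL12A1 (-4.74 ± 0.33). At day 18 ribosomal RNA made up 0.502 ± 0.0413% of TPM against 0.206 ± 0.0511% in DMSO (SD, n = 3). In all, 2585 genes were at least 2-fold higher and 1992 lower than in DMSO, and 2511 higher and 1766 lower than on ribociclib (1140 and 513 with limma on TPM).

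**Figure D5:**
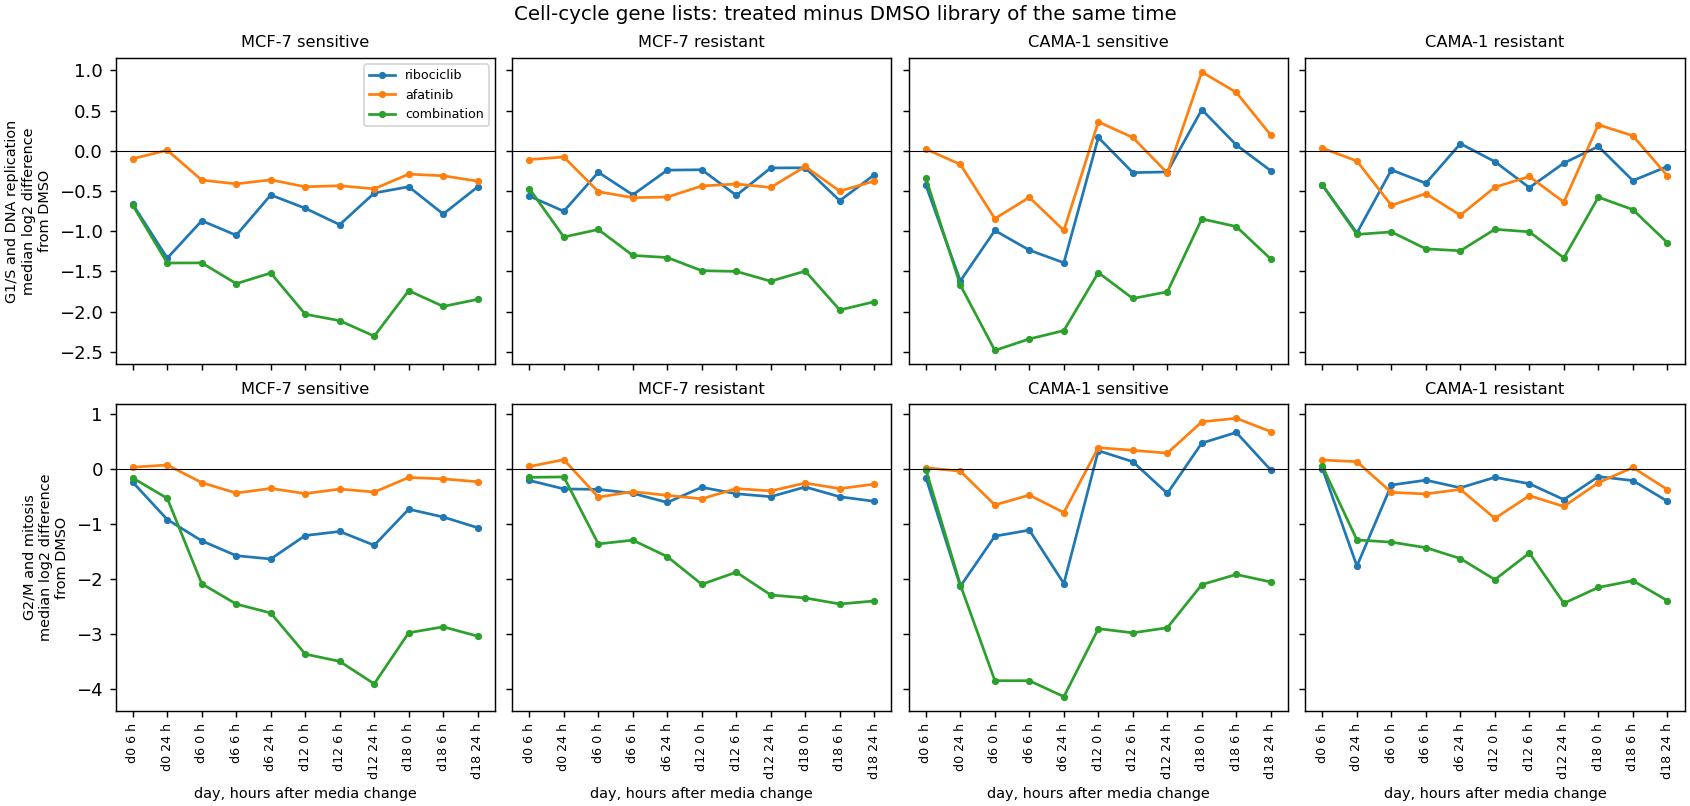
Median log2 difference of the G1/S (top) and G2/M (bottom) lists between each treated library and the DMSO library of the same time (vertical), by day and hours after media change (horizontal), for each line and state. In sensitive CAMA-1 cells the combination held the G2/M list between -4.14 and -1.92 from day 6 to day 18, while the ribociclib points lay between -0.45 and 0.66 from day 12.

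In sensitive CAMA-1 cells the combination lowered replication and mitosis genes and raised CDKN1A, cholesterol synthesis and drug metabolism genes. CDKN1A rose by 2.37 ± 0.29 and ERBB2 by 0.85 ± 0.10, while MKI67 changed by -3.57 ± 0.27 and CCNE2 by -2.26 ± 0.17 (largest adjusted p = 7.1e-11). All of the G2/M list moved down: 0 rose and 40 fell of 40 (the same adjusted over the list alone), median -2.98 (camera adjusted p = 2.9e-38, adjusted p = 0.095 with an estimated correlation). Most of the G1/S list did too: 0 rose and 41 fell of 45 (the same adjusted over the list alone), median -1.72 (camera adjusted p = 1.5e-28, adjusted p = 0.16 with an estimated correlation). RRM2 (-4.54 ± 0.34), MYBL2 (-4.46 ± 0.29) and TYMS (-4.20 ± 0.29) were among the lowest of all genes, RRM2 and TYMS being enzymes of nucleotide supply. Against ribociclib alone, in the G2/M list 0 rose and 40 fell of 40 (the same adjusted over the list alone), median -2.59 (camera adjusted p = 7.8e-42, adjusted p = 0.069 with an estimated correlation). Among cholesterol synthesis genes 22 rose and 0 fell of 24 (22 and 1 adjusted over the list alone), median 0.82 (camera adjusted p = 7.0e-05, adjusted p = 0.46 with an estimated correlation), with SC5D (2.39 ± 0.15). Lysosome and autophagy genes moved likewise: 29 rose and 0 fell of 30 (the same adjusted over the list alone), median 0.83 (camera adjusted p = 1.1e-08, adjusted p = 0.19 with an estimated correlation), with CTSL (1.43 ± 0.10). Among drug efflux and metabolism genes 10 rose and 0 fell of 11 (the same adjusted over the list alone), median 1.57 (camera adjusted p = 4.3e-04, adjusted p = 0.17 with an estimated correlation), with CYP1A1 (4.19 ± 0.36) and UGT1A6 (2.69 ± 0.18). Cytosolic ribosomal protein genes moved down: 0 rose and 33 fell of 33 (the same adjusted over the list alone), median -0.59 (camera adjusted p = 4.3e-28, adjusted p = 0.095 with an estimated correlation). Hypoxia and glycolysis genes were lower than in DMSO: 2 rose and 19 fell of 27 (the same adjusted over the list alone), median -1.02 (camera adjusted p = 3.4e-07, adjusted p = 0.50 with an estimated correlation), or -1.63 without day 6 and -0.62 without day 18. Mitochondrially encoded mRNAs, taken as a sign of RNA quality, were lower too: 2 rose and 9 fell of 13 (the same adjusted over the list alone), median -0.62 (camera adjusted p = 0.015, adjusted p = 0.77 with an estimated correlation). Their median was -0.24 (adjusted p = 0.16) without day 18 and -0.87 (0.10) with median-ratio scaling. At day 18 they made up 8.64 ± 1.81% of TPM against 17.7 ± 1.77% in DMSO (SD, n = 3), and ribosomal RNA 1.37 ± 0.246% against 0.161 ± 0.0137%. In all, 1309 genes were at least 2-fold higher and 716 lower than in DMSO, or 770 and 976 with median-ratio scaling. Against ribociclib the counts were 1161 and 597, or 574 and 880 with that scaling, or 880 and 738 with mitochondrial, ribosomal RNA and microRNA genes left out and TPM rescaled.

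In resistant CAMA-1 cells on the combination CDKN1A rose by 2.24 ± 0.29 and ERBB2 by 1.10 ± 0.10, while MKI67 changed by -2.23 ± 0.27 and CCNE2 by -1.26 ± 0.17 (largest adjusted p = 2.1e-09). For the G2/M list 0 rose and 40 fell of 40 (the same adjusted over the list alone), median -1.87 (camera adjusted p = 4.0e-32, adjusted p = 0.23 with an estimated correlation), with UBE2C (-2.54 ± 0.28). For the G1/S list 1 rose and 41 fell of 45 (2 and 41 adjusted over the list alone), median -1.02 (camera adjusted p = 8.8e-23, adjusted p = 0.29 with an estimated correlation). Against ribociclib alone, in the G2/M list 0 rose and 40 fell of 40 (the same adjusted over the list alone), median -1.56 (camera adjusted p = 1.0e-32, adjusted p = 0.16 with an estimated correlation). Among cholesterol synthesis genes 21 rose and 1 fell of 24 (the same adjusted over the list alone), median 0.74 (camera adjusted p = 5.8e-04, adjusted p = 0.46 with an estimated correlation), with TM7SF2 (2.24 ± 0.10). Among interferon response genes 20 rose and 0 fell of 26 (the same adjusted over the list alone), median 0.90 (camera adjusted p = 3.0e-04, adjusted p = 0.34 with an estimated correlation), with PARP9 (2.01 ± 0.13). Among hypoxia and glycolysis genes 1 rose and 19 fell of 27 (the same adjusted over the list alone), median -0.98 (camera adjusted p = 5.4e-10, adjusted p = 0.36 with an estimated correlation), or -1.52 without day 6 and -0.63 without day 18. Ribosomal protein genes moved down: 0 rose and 33 fell of 33 (the same adjusted over the list alone), median -0.62 (camera adjusted p = 1.7e-38, adjusted p = 0.026 with an estimated correlation). Mitochondrially encoded mRNAs moved with them: 2 rose and 7 fell of 13 (2 and 8 adjusted over the list alone), median -0.39 (camera adjusted p = 9.6e-04, adjusted p = 0.54 with an estimated correlation), or a median of -0.92 without day 6 and 0.08 without day 18. Ribosomal RNA made up 1.28 ± 0.123% of TPM at day 18 against 0.215 ± 0.0850% in DMSO (SD, n = 3). The lowest changes included MGP (-5.24 ± 0.24). In all, 1051 genes were at least 2-fold higher and 473 lower than in DMSO, or 573 and 730 with median-ratio scaling. Against ribociclib the counts were 978 and 337, or 426 and 622 with that scaling and 1588 and 410 without day 6.

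Within the first day, at 6 and 24 h of day 0 (n = 2 a group), ribociclib lowered replication genes in MCF-7. CCNE2 changed by -2.37 ± 0.32 in sensitive cells (adjusted p = 2.5e-06). In the G1/S list of sensitive cells 0 rose and 28 fell of 45 (0 and 43 adjusted over the list alone), median -0.96 (camera adjusted p = 3.0e-92, adjusted p = 5.3e-04 with an estimated correlation). Of the same genes in resistant cells 0 rose and 5 fell of 45 (0 and 39 adjusted over the list alone), median -0.64 (camera adjusted p = 1.5e-44, adjusted p = 0.063 with an estimated correlation). On the combination 0 rose and 29 fell of 45 (0 and 45 adjusted over the list alone), median -1.0 (camera adjusted p = 1.6e-70, adjusted p = 0.0042 with an estimated correlation) in sensitive cells. In resistant cells the same drugs raised the PI3K-inhibiting gene PIK3IP1 (1.77 ± 0.23). Afatinib lowered ERK pathway output in resistant cells: 0 rose and 1 fell of 21 (0 and 10 adjusted over the list alone), median -0.58 (camera adjusted p = 7.1e-11, adjusted p = 4.7e-04 with an estimated correlation). For ribociclib 2 genes were at least 2-fold higher and 47 lower in sensitive cells (83 in total from 24 h alone, 8 from 6 h alone), and 7 and 6 in resistant cells (5 and 3 alone). Combination counts were 20 and 49 in sensitive cells (3 in total from 6 h alone), and 111 and 50 in resistant cells (11 from 6 h alone). For afatinib edgeR called 0 genes in sensitive cells (872 at an unadjusted p under 0.05, 2 called by DESeq2). In resistant cells it called 1, PHLDA1, which was lower, was chosen after its values were seen, and did not pass from 6 h alone (1697 genes unadjusted, 9 by DESeq2).

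On day 0 in CAMA-1, the G1/S list had a negative median under ribociclib, and hardly any member passed alone. On ribociclib, in the G1/S list of sensitive cells 0 rose and 1 fell of 45 (0 and 39 adjusted over the list alone), median -1.01 (camera adjusted p = 1.1e-68, adjusted p = 0.020 with an estimated correlation). Of the same genes in resistant cells 0 rose and 0 fell of 45 (the same adjusted over the list alone), median -0.72 (camera adjusted p = 1.1e-27, adjusted p = 0.67 with an estimated correlation). Leaving out 1 time, the sensitive median was -1.62 at 24 h and -0.43 at 6 h, and the resistant one -0.43 at 6 h. FAM111B, a gene of DNA replication, changed by -3.04 ± 0.59 in sensitive cells (adjusted p = 0.021), and by -1.54 at 6 h alone. Ribosomal RNA made up 0.904 ± 0.972% of TPM in sensitive cells on ribociclib (SD, n = 2), the 2 lying far apart, against 0.171 ± 0.00615% in DMSO. With limma, ribociclib in sensitive cells left 8 genes higher and 4 lower, or 1 and 1 with TPM rescaled as above. The counts were 0 for ribociclib in resistant cells (647 at an unadjusted p under 0.05, 1 called at 24 h alone) and 0 for afatinib in sensitive and resistant cells (352 and 315 unadjusted, 1 called in resistant cells at 24 h alone). For the combination they were also 0 (843 and 1006 unadjusted, 24 called in sensitive cells at 24 h and 1 at 6 h alone).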

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

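The tests of drift in DMSO, of the effect at day 6, of single days of collection and of mitochondrial mRNAs were chosen after the results were seen, and so was median-ratio scaling. For shares of higher genes the range of 45 to 55% was set beforehand, but taking 55% as the bound against was chosen after.

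In CAMA-1 cells hypoxia and glycolysis genes were lower than in DMSO at days 6 to 18 on afatinib and the combination, and in sensitive cells on ribociclib, though no such list call held with an estimated correlation (adjusted p = 0.067 to 0.50). An effect already present at day 6 is argued against: the list's median difference from DMSO on the combination was 0.0619 ± 0.354 (SD, n = 3) in sensitive cells and 0.0230 ± 0.142 in resistant cells. At days 6, 12 and 18 ribociclib gave -0.21 ± 0.33, -1.59 ± 0.41 and -1.22 ± 0.34 in sensitive cells (SD, n = 3). Resistant cells stayed close to DMSO, at -0.10 ± 0.04, -0.25 ± 0.07 and -0.15 ± 0.05. A candidate explanation is the rise of the list in the DMSO cultures themselves, which came to 2.04 from day 0 to day 18 in sensitive cells (on the combination, 0.29) and 2.33 in resistant cells (on the combination, 0.61). Whether cell density or oxygen set that rise, and whether a drug acts on these genes after day 6, stays open and was not tested.

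In MCF-7 cells afatinib lowered the interferon response list in sensitive cells (median -0.90, -0.49 without day 18) and raised it in resistant cells. Both calls were lost with an estimated correlation (adjusted p = 0.27 and 0.16). Sensitive cells gave -0.23 ± 0.28, -0.68 ± 1.03 and -1.35 ± 0.11 at days 6, 12 and 18 (SD, n = 3). The tested difference had a median of 1.74 for afatinib and 2.78 for the combination. White blood cells are argued against, as their marker PTPRC reached at most 0.0559 CPM in any of the 8 groups. A single day is argued against, as the median stayed between 1.26 and 2.08 with 1 day left out, and so is RNA quality, as the mitochondrial mRNAs differed by 0.249 against 1.74 for the list. Drift stays open for sensitive cells, where the list rose in DMSO from day 6 to day 18. A difference between the states stays a hypothesis, with no second MCF-7 culture of either. In CAMA-1 the fall did not recur. Afatinib gave 0.34, 0.35 and 0.29 in sensitive and 0.41, 0.85 and 0.56 in resistant cells at days 6, 12 and 18.

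In sensitive CAMA-1 cells on the combination, 64.6% of the called genes were higher. Mitochondrial, ribosomal RNA and microRNA genes taking a share of TPM are argued against as the whole cause. With them left out and TPM rescaled, 62.0% of 2069 called genes were higher (95% binomial interval 59.9 to 64.1%), where that cause needs 45 to 55%. It stays open for the combination against ribociclib, where the share went from 66.0% to 54.4%. Other abundant transcripts stay open too, as ribosomal protein genes, which fell here, were not left out. Genes of low level are argued against, since among genes of at least 10 TPM 60.3% of 1043 were higher (57.3 to 63.3%). Either interval reached below the 60% set beforehand as the bound against, and takes genes as independent. Scaling stays open. Median-ratio scaling gave 770 higher and 976 lower, but it centres all genes and so cannot decide. No biological explanation was tested.

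The effect of treatment differed at least 2-fold between resistant and sensitive cells for 445 genes under ribociclib, 423 under afatinib and 2097 under the combination in MCF-7. In CAMA-1 the numbers were 233, 142 and 380. PGR fell by 0.87 under ribociclib in sensitive MCF-7 cells and rose by 2.04 in CAMA-1, a difference between lines that was not tested. ERBB3 changed by -0.42 under afatinib in resistant MCF-7 cells and by 0.37 in CAMA-1, and by -0.78 and 0.40 under the combination, again untested between lines. In the untreated library of resistant MCF-7 cells the ERK pathway output list stood at 0.38. The highest tested DMSO library of those cells had 0.18.

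Among 56 tests for a library far from the others of its group, 5 found 1. Chance flags about 1 in 20. The list of mitochondrial mRNAs was high in sensitive MCF-7 cells in DMSO at day 6, 24 h (mean log2 level 11.5, group mean 10.9 ± 0.277 SD, n = 9). At day 18, 24 h, it was low in resistant CAMA-1 cells in DMSO (12.9, group mean 13.3 ± 0.214) and on ribociclib (13.0, group mean 13.4 ± 0.198). The total count was high in sensitive MCF-7 cells on ribociclib at day 18, 6 h (34.5 M, group mean 21.2 ± 5.43 M). The G2/M list was low in sensitive CAMA-1 cells on ribociclib at day 6, 24 h (3.75, group mean 4.88 ± 0.525).

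Counts at days 6 to 18 were set against exchanges of 2 groups' libraries within collection times, with limma and time block in both lines. In each of the 20 comparisons, 1 of 100 splits, the real one, gave a count as large. The order below is resistant against sensitive, then, each in sensitive and in resistant cells, ribociclib, afatinib, the combination and the combination against ribociclib, then the ribociclib difference between states. Real counts are given with the highest of the other splits in brackets. In MCF-7 they were 2133 (1155), 1041 (646), 300 (142), 946 (315), 1053 (312), 3783 (2731), 3777 (2841), 2339 (1676), 3529 (2603) and 491 (1). In CAMA-1 they were 589 (334), 440 (1), 87 (2), 475 (85), 831 (537), 2017 (1181), 1530 (710), 1763 (779), 1321 (857) and 214 (2). Splits that ignored the collection times gave as many genes in up to 5 of 100, for the combination in resistant cells of CAMA-1.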

How the results depend on the processing

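A pseudocount of 0.1 and median-ratio scaling were chosen after seeing the data. RLE scaling, DESeq2 and limma on TPM were run for MCF-7 only, because RLE and DESeq2 need counts and the CAMA-1 table held TPM. In MCF-7, DESeq2 kept the direction and side of the threshold of 1312 named-gene and 252 list results (3 and 2 fell below it), RLE scaling of 1338 named-gene and 253 list results (7 and 2) and limma on TPM of 1197 named-gene and 242 list results (44 and 7). In CAMA-1, a pseudocount of 0.1 kept 1344 named-gene and 249 list results (4 and 2) and median-ratio scaling 1303 named-gene and 234 list results (29 and 13). With the 3 days as replicates, 162 and 6 fell below the threshold in MCF-7 and 165 and 4 in CAMA-1. Depth limits only what can be said of rare transcripts in MCF-7, and it is unknown for CAMA-1.

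Libraries of different groups taken at the same time had residuals with a mean correlation of 0.127 in MCF-7 (lowest pair of groups -0.0811, other times -0.0155) and 0.150 in CAMA-1 (-0.163, other times -0.0186). Fitted with no block for this pairing, 99 and 4 results fell below the threshold in MCF-7 and 72 and 3 in CAMA-1.

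The following counts of called genes moved by more than 1.5 times, and the cause was not tested except that fewer libraries (1 time or day left out, day 0 alone, days as replicates) leave less to test with. Each comparison is against DMSO at days 6 to 18 unless stated, in sensitive (S) or resistant (R) cells. With RLE scaling they went in MCF-7 at day 0: 1 to 4 (afatinib R). With DESeq2 they went in MCF-7 at day 0: 13 to 21 (ribociclib R), 0 to 2 (afatinib S), 1 to 9 (afatinib R). With no filter on low values they went in MCF-7 at day 0: 49 to 32 (ribociclib S), 13 to 8 (ribociclib R), 69 to 31 (combination S), 161 to 79 (combination R), and in CAMA-1 at day 0: 12 to 38 (ribociclib S), 0 to 41 (ribociclib R), 0 to 35 (afatinib S), 0 to 47 (afatinib R), 0 to 45 (combination S), 0 to 44 (combination R). With limma on log2(TPM + 1) they went in MCF-7: 2576 to 834 (resistant against sensitive), 1325 to 414 (ribociclib S), 402 to 67 (ribociclib R), 1210 to 305 (afatinib S), 1397 to 365 (afatinib R), 4284 to 1968 (combination S), 4577 to 1922 (combination R), 2812 to 946 (combination against ribociclib S), 4277 to 1653 (combination against ribociclib R), 445 to 141 (ribociclib difference between states), and in MCF-7 at day 0: 1 to 6 (afatinib R), 161 to 74 (combination R). With no block for collection time they went in MCF-7 at day 0: 49 to 9 (ribociclib S), 13 to 5 (ribociclib R), 1 to 0 (afatinib R), 69 to 10 (combination S), 161 to 35 (combination R), and in CAMA-1 at day 0: 12 to 0 (ribociclib S). With the 3 days as replicates they went in MCF-7: 402 to 237 (ribociclib R), 445 to 43 (ribociclib difference between states), and in CAMA-1: 69 to 25 (ribociclib R), 233 to 25 (ribociclib difference between states). With all 11 times together they went in MCF-7: 1325 to 737 (ribociclib S), 402 to 223 (ribociclib R), 1210 to 653 (afatinib S), 1397 to 819 (afatinib R), 4284 to 2732 (combination S), 4577 to 2990 (combination R), 2812 to 1621 (combination against ribociclib S), 4277 to 2644 (combination against ribociclib R), 445 to 146 (ribociclib difference between states), and in CAMA-1: 453 to 273 (ribociclib S), 69 to 39 (ribociclib R), 482 to 291 (afatinib S), 832 to 460 (afatinib R), 1758 to 1132 (combination against ribociclib S), 1315 to 789 (combination against ribociclib R), 233 to 98 (ribociclib difference between states). With day 0 fitted alone they went in MCF-7 at day 0: 49 to 8 (ribociclib S), 13 to 4 (ribociclib R), 1 to 0 (afatinib R), 69 to 4 (combination S), 161 to 47 (combination R), and in CAMA-1 at day 0: 12 to 0 (ribociclib S). With a pseudocount of 0.1 they went in CAMA-1: 570 to 1026 (resistant against sensitive), 453 to 763 (ribociclib S), 69 to 143 (ribociclib R), 482 to 1016 (afatinib S), 832 to 1594 (afatinib R), 1524 to 2407 (combination R), 1315 to 2154 (combination against ribociclib R), 233 to 400 (ribociclib difference between states), and in CAMA-1 at day 0: 0 to 1 (ribociclib R), 0 to 1 (combination S), 0 to 1 (combination R). With median-ratio scaling they went in CAMA-1 at day 0: 12 to 7 (ribociclib S), 0 to 1 (combination S). Leaving out 1 day, or 1 time at day 0, gave, as lowest to highest for the count with all libraries, in MCF-7: 167 to 623 for 445 (ribociclib difference between states), and in MCF-7 at day 0: 8 to 83 for 49 (ribociclib S), 3 to 5 for 13 (ribociclib R), 0 to 1 for 1 (afatinib R), 3 to 79 for 69 (combination S), 11 to 154 for 161 (combination R), and in CAMA-1: 363 to 702 for 453 (ribociclib S), 44 to 77 for 69 (ribociclib R), 432 to 728 for 482 (afatinib S), 555 to 1499 for 832 (afatinib R), 931 to 1998 for 1315 (combination against ribociclib R), 110 to 494 for 233 (ribociclib difference between states), and in CAMA-1 at day 0: 14 to 34 for 12 (ribociclib S), 0 to 1 for 0 (ribociclib R), 0 to 1 for 0 (afatinib R), 1 to 24 for 0 (combination S).

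A smaller set of results changed sign or reached 0, and the cause was not tested. These were, with limma on log2(TPM + 1): CDK4 -0.13 (resistant against sensitive MCF-7), ERBB2 0.18 (combination R MCF-7), CDK6 0.13 (combination against ribociclib S MCF-7), GREB1 0.0535 (combination against ribociclib R MCF-7). With no filter on low values: senescence-associated secretory genes list 0 (afatinib R CAMA-1), ERK pathway output list -0.0826 (combination against ribociclib S CAMA-1). With all 11 times together: estrogen receptor targets list 0.000732 (combination R CAMA-1). With median-ratio scaling: RB1 -0.19 (afatinib R CAMA-1), CDK4 -0.25 (combination R CAMA-1), CDK4 -0.29 (combination against ribociclib S CAMA-1). With 1 day or time left out, the lowest and highest values were mitochondrially encoded mRNAs (RNA quality) list -0.20 to 0.11 (afatinib R MCF-7), ERBB2 -0.13 to 0.18 (combination R MCF-7), hypoxia and glycolysis list -0.14 to 0.25 (ribociclib difference between states MCF-7), lysosome and autophagy list -0.0207 to 0.22 (afatinib S MCF-7 at day 0), NRF2 targets list -0.12 to 0.49 (afatinib R MCF-7 at day 0), CDKN1A -0.69 to 1.02 (ribociclib S CAMA-1), ESR1 -0.61 to 0.46 (afatinib S CAMA-1), GREB1 -0.69 to 0.67 (afatinib S CAMA-1), G1/S and DNA replication (E2F targets) list -0.34 to 0.37 (afatinib S CAMA-1), antigen presentation list -0.13 to 0.0153 (combination against ribociclib S CAMA-1), G2/M and mitosis list -0.52 to 0.41 (ribociclib difference between states CAMA-1), ERK pathway output list -0.0295 to 0.17 (combination against ribociclib S CAMA-1), interferon response list -0.0755 to 0.0302 (ribociclib R CAMA-1), G2/M and mitosis list -0.16 to 0.58 (afatinib S CAMA-1), estrogen receptor targets list -0.0397 to 0.38 (afatinib S CAMA-1), mitochondrially encoded mRNAs (RNA quality) list -0.92 to 0.0818 (combination R CAMA-1), cytosolic ribosomal proteins list -0.00167 to 0.13 (afatinib R CAMA-1 at day 0), mitochondrially encoded mRNAs (RNA quality) list -0.35 to 0.0129 (afatinib R CAMA-1 at day 0), G1/S and DNA replication (E2F targets) list -0.17 to 0.0202 (afatinib S CAMA-1 at day 0), G2/M and mitosis list -1.29 to 0.0413 (combination R CAMA-1 at day 0).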

Other observations

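Apart from the media-change test of immediate-early genes and the tests of TGF-beta response and histone genes, the tests here were chosen after the results were seen. The DMSO cultures themselves changed over the days. Mitotic genes of the G2/M list, day 18 against day 6, had a median of -1.21 (camera adjusted p = 1.7e-18, adjusted p = 0.26 with an estimated correlation) in sensitive CAMA-1 cells and a median of -1.17 (camera adjusted p = 8.0e-15, adjusted p = 0.25 with an estimated correlation) in resistant ones. In MCF-7 the same list had a median of -0.33 (camera adjusted p = 4.2e-11, adjusted p = 0.25 with an estimated correlation) in sensitive and a median of -0.44 (camera adjusted p = 6.4e-13, adjusted p = 0.14 with an estimated correlation) in resistant cells. Immediate-early genes, which growth factors induce through ERK, had a median of 0.79 (camera adjusted p = 1.4e-14, adjusted p = 0.020 with an estimated correlation) in resistant MCF-7 cells and a median of 0.07 (camera adjusted p = 0.065) in sensitive ones. In CAMA-1 they had a median of 0.80 (camera adjusted p = 2.2e-05, adjusted p = 0.25 with an estimated correlation) in resistant and a median of 0.58 (camera adjusted p = 0.0059, adjusted p = 0.46 with an estimated correlation) in sensitive cells. At least 2-fold, 159 genes were higher and 51 lower at day 18 in sensitive MCF-7 cells, 579 and 160 in resistant MCF-7 cells, 402 and 531 in sensitive CAMA-1 cells and 386 and 723 in resistant CAMA-1 cells.

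Ribociclib in resistant MCF-7 cells also moved genes of the TGF-beta response: 9 rose and 0 fell of 20 (10 and 0 adjusted over the list alone), median 0.18 (camera adjusted p = 1.8e-05, adjusted p = 0.020 with an estimated correlation). Resistant MCF-7 cells in DMSO had less of the replication-dependent histone transcripts: 2 rose and 20 fell of 28 (the same adjusted over the list alone), median -0.89 (camera adjusted p = 2.4e-04, adjusted p = 0.20 with an estimated correlation). These histone transcripts lack a poly(A) tail, and the libraries were made from polyadenylated RNA.

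A first hypothesis was that the drugs together lower the G2/M list by more than the sum of their single effects on the log2 scale. Combination minus ribociclib minus afatinib plus DMSO gave a median of -1.41 in sensitive MCF-7 cells (camera adjusted p = 4.0e-71, adjusted p = 0.012 with an estimated correlation), -1.02 in resistant MCF-7 cells (camera adjusted p = 7.6e-28, adjusted p = 0.18 with an estimated correlation), -2.76 in sensitive CAMA-1 cells (camera adjusted p = 2.7e-48, adjusted p = 0.16 with an estimated correlation) and -1.14 in resistant CAMA-1 cells (camera adjusted p = 6.3e-46, adjusted p = 0.12 with an estimated correlation). In that order 585, 1187, 919 and 5 genes departed from the sum by at least 2-fold, and 40, 40, 40 and 0 of 40 list members fell below it. The excess depended on the day, at -0.53 ± 0.09, -1.93 ± 0.20 and -1.88 ± 0.18 in sensitive MCF-7 cells, -0.47 ± 0.03, -1.22 ± 0.16 and -1.62 ± 0.12 in resistant MCF-7 cells, -1.83 ± 0.51, -3.26 ± 0.47 and -3.21 ± 0.44 in sensitive and -0.76 ± 0.15, -0.97 ± 0.21 and -1.67 ± 0.22 in resistant CAMA-1 cells (days 6, 12 and 18, SD, n = 3). In sensitive CAMA-1 cells, whose DMSO control fell, the single effects were above 0 at day 18, at 0.37 ± 0.35 for ribociclib and 0.81 ± 0.13 for afatinib. The medians over all days are consistent with the hypothesis, found and tested on the same data. With an estimated correlation only the call in sensitive MCF-7 cells held, and in resistant CAMA-1 cells no member passed alone.

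A second hypothesis was that the effect of the combination on this list grows with days of treatment. From day 6 to day 18 the median effect changed by -0.89 in resistant MCF-7 cells (camera adjusted p = 1.9e-15, adjusted p = 0.12 with an estimated correlation) and -0.64 in resistant CAMA-1 cells (camera adjusted p = 3.6e-24, adjusted p = 0.14 with an estimated correlation), which is consistent with growth. In sensitive MCF-7 cells it changed by -0.43 (camera adjusted p = 5.0e-07, adjusted p = 0.42 with an estimated correlation), too little to decide by the bounds set, and the effect was largest at day 12 (-2.39 ± 0.27 at day 6 (SD, n = 3), -3.59 ± 0.28 at day 12 and -2.97 ± 0.09 at day 18). In sensitive CAMA-1 cells it changed by 1.98 (camera adjusted p = 1.3e-24, adjusted p = 0.12 with an estimated correlation), the opposite direction, against the falling DMSO control described above.

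New medium was expected to raise immediate-early genes at 6 h. Their median at 6 h against 0 h was 0.0366 in MCF-7 (camera adjusted p = 0.99) and 0.0786 in CAMA-1 (0.40). This argues against it at 6 h. The hours between 0 and 6 h were not sampled. The hypoxia and glycolysis list was expected to fall at 6 h. Its median was -0.14 in MCF-7 (0.011), less than the bound set, and -0.28 in CAMA-1 (0.0033), which did not decide. MYC, chosen after its values were seen, was lower at 6 h in MCF-7 (-1.02 ± 0.07, adjusted p = 1.2e-18).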
